A study of Homo sapiens with 6 samples.

How the data were processed

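Polyadenylated RNA of 6 libraries was sequenced after strand-specific library preparation, 3 from cells given an empty plasmid and 3 from cells given an NR3C1 plasmid, per the labels' protocols. Those protocols describe lipid-based transfection of HT22 cells and a harvest at 48 h for the RT-qPCR check of NR3C1. The harvest time of the sequenced cells and the RT-qPCR values are not given in the sources used here.

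The authors deposited read counts per gene, whole numbers with no normalization, for 22493 genes, and FPKM values, reads scaled by gene length and by library total, for 22236 of them. Per the submitters' processing notes the tools were bcl2fastq, TopHat2 and edgeR, with no role, version or setting given, and the genome build was GRCh38, which is human. The labels also call the organism human. All 22493 gene identifiers in the deposited count table are mouse Ensembl identifiers with mouse symbols and chromosomes, so the genes are treated as mouse genes. The mouse build, the annotation release, the counting tool and its strand setting are not given in the sources used here. A human reference genome was at hand and was not used, so positions are limited to the chromosome the deposited tables name. Reads of the plasmid would be counted under Nr3c1 only as far as its sequence aligned to the mouse gene model. Gene symbols are those of the tables, and 21 symbols occur more than once.

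Total counts ranged from 27598609 to 34825041 per library, and 17276 to 17881 genes had reads in a library. Pairwise Pearson correlations of log2 CPM ranged from 0.993 to 0.996, and a chi-square test of the counts of each pair gave 4.69 to 29.9 per degree of freedom, so no pair agreed within sampling noise and all 6 libraries were counted separately.

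Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, two-sided, TMM scaling, all 6 libraries, group as the only term). Genes were kept by filterByExpr with its minimum count of 10, which left 12611. The Benjamini-Hochberg threshold was 0.05. CPM values are TMM-scaled and given as mean ± SD over 3 libraries. Standard errors of log2 fold changes were derived from the test statistic, and intervals are 95%. The common biological coefficient of variation was 6.34%. FPKM values were used for Nr3c1 and as an alternative, tested on log2(FPKM + 1) and log2(FPKM + 0.1) with limma 3.58.1, where fold changes of low genes are understated.

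The design, the tests, the alternatives below except edgeR's exact test, the rule for named genes and 22 gene lists were fixed from textbook knowledge before the data were examined. There were 5 lists of main interest: glucocorticoid receptor induced genes, inflammatory transcription factors, inflammatory cytokines and NF-kB target genes, interferon-stimulated genes, and splicing factors. The other 17 cover stress responses, proliferation, metabolism, cell type markers and RNA quality. Lists with at least 5 tested members, 21 of them, were tested with limma's camera on voom values with a preset correlation of 0.01 between genes, adjusted over the 21 lists. camera asks whether a list's genes differ from all other genes, and fry whether they move on balance one way. Both, and camera with an estimated correlation, were run. Within each list the edgeR p-values were also adjusted over the list alone.

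Named genes were Nr3c1, the 12 called genes with the largest change in each direction, and up to 4 called members per list, up to 15 for the inflammatory transcription factors, or the 2 with the smallest p where fewer than 2 were called. As 0 genes were called, the rule for the largest changes named 0 genes and each list gave its 2 members with the smallest p, as values. Some of the genes this rule gives are not reported here. Marker lists for macrophages (20 genes) and lymphoid cells (14 genes) were written after the counts had been seen. Of the macrophage markers 6 are also in the glial and microglial list and 1 is in another fixed list.

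The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter on low counts, at least 1 CPM in 3 libraries, the replicate number as a block, the deposited FPKM values with and without a minimum mean of 0.5, stricter thresholds, each library left out in turn, an estimated correlation, fry, and edgeR's exact test. The gene test and the list test were tested on simulated data with known changes drawn from these libraries. With 12514 simulated genes, 195 were called: 174 of the genes changed one by one, 9 members of a list raised by a small amount, and 12 unchanged genes. A simulated list raised by 0.2 on the log2 scale passed camera and 0 of 200 unchanged lists fell under 0.05. The simulated genes varied independently of each other, so this cannot show how camera behaves where the genes of a list vary together. In the real libraries the correlation estimated for the interferon list was 0.245. Gene length, taken from the ratio of counts to FPKM, was used to match genes outside the interferon list, each draw taking 1 of the 50 genes nearest to each member in length and expression. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. Differences in splicing were not analysed here, since the tables hold genes.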

Results

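Gene expression was measured by strand-specific sequencing of polyadenylated RNA in 6 libraries labelled as HT22, an immortalised line derived from mouse hippocampal neurons. In 3 libraries the cells had received an empty plasmid, and in 3 a plasmid carrying NR3C1, the gene of the glucocorticoid receptor, a ligand-activated transcription factor. The series title places the question at inflammatory transcription factors and their splicing. Gene-level tables were used here, so splicing patterns were not analysed. The total count per library was 34550534, 27598609 and 34825041 in control replicates 1, 2 and 3, and 31011267, 31696201 and 32421740 in NR3C1 replicates 1, 2 and 3. The labels do not say that the replicates were separate cultures, so p-values measure only the spread between these libraries, which can be technical.

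Nr3c1, as counted under the mouse gene, was not detectably higher in the libraries labelled NR3C1. Its level in CPM, counts scaled to a common library total, was 20.2 ± 2.35 CPM in the control libraries and 21.7 ± 1.94 CPM in the others (SD, n = 3 each). Interferon-stimulated genes rose together by a median of 12.3% in the libraries labelled NR3C1 against all other genes, with 63 of 68 tested members on the positive side, in limma's camera test with a small preset correlation between genes. That call was lost with an estimated correlation (adjusted p = 0.231). Inflammatory transcription factors and genes known to be induced by glucocorticoids did not pass that test. In edgeR's quasi-likelihood test 0 of 12611 genes passed the threshold, 534 had an unadjusted p under 0.05, and other tools called 0 to 29 genes, with 23 by DESeq2 and 29 by edgeR's exact test. The quasi-likelihood test called 65 with no filter on low counts and 30 without control replicate 2.

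Nr3c1 (ENSMUSG00000024431.12, chromosome 18) had counts of 766, 481 and 740 in control replicates 1, 2 and 3 and of 657, 633 and 762 in NR3C1 replicates 1, 2 and 3. The deposited FPKM values gave 2.94 ± 0.361 in the control libraries and 3.11 ± 0.242 in the libraries labelled NR3C1 (SD, n = 3 each). The log2 fold change was 0.10 with a standard error of 0.09, and edgeR's quasi-likelihood test gave an adjusted p = 0.998. Its 95% interval, from 0.928-fold to 1.23-fold, was narrow enough to leave out a 1.5-fold rise in reads counted for the mouse gene. Because the counted Nr3c1 was not detectably raised, the treated group is called the libraries labelled NR3C1, and each direction given for it rests on the label alone.

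**Figure D1:**
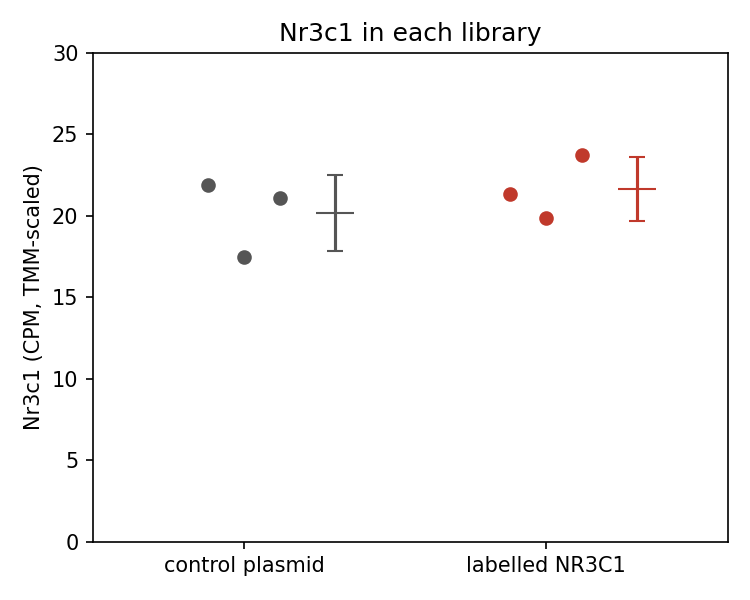
Nr3c1 in CPM (vertical axis) in each of the 6 libraries, by plasmid group; points are libraries and the bars beside them are the mean ± SD. The 2 groups overlap, at 20.2 ± 2.35 CPM with the control plasmid and 21.7 ± 1.94 CPM in the libraries labelled NR3C1.

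Transcripts typical of macrophages were among the most abundant in every library of both groups. Lyz2, which encodes the lysozyme of myeloid cells, averaged 12231 ± 413 CPM (SD over 6 libraries) and ranked 3 among all genes. Cd14, a co-receptor for lipopolysaccharide, averaged 2717 ± 34.1 CPM, the colony-stimulating factor receptor gene Csf1r 1134 ± 78.9 CPM and Spi1, the myeloid transcription factor PU.1, 533 ± 31.0 CPM. Of 20 macrophage markers, 18 averaged at least 100 CPM, and their median lay between 786 and 829 CPM in the 6 libraries. Of the 39 neuronal markers in the count table, 8 averaged at least 1 CPM and 0 reached 100 CPM, with a median of 0.0436 CPM. L1cam was the highest of them at 18.7 ± 0.503 CPM, while Rbfox3, the gene of the neuronal nuclear antigen NeuN, averaged 0.0321 CPM and Tubb3, neuronal beta-tubulin, 0.195 CPM. Of 40 extracellular matrix and mesenchymal markers 9 averaged at least 1 CPM, of 30 glial and microglial markers 19, with 8 at 100 CPM or more, of 18 epithelial markers 2, and of 9 lymphoid markers 1, the T cell kinase gene Lck. The glial and microglial list shares 6 markers with the macrophage list, among them Csf1r. Of its other members, the microglial gene Tmem119 averaged 0.984 ± 0.197 CPM, P2ry12 2.77 ± 0.448 CPM and the astrocyte gene Gfap 0.242 ± 0.148 CPM. The neuronal, glial and microglial, matrix and epithelial lists were fixed in advance, and the macrophage and lymphoid lists were written afterwards, as were the choices of Lyz2, Cd14, Spi1, Tmem119, P2ry12, Gfap, L1cam, Rbfox3, Tubb3 and Lck as examples.

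**Figure D2:**
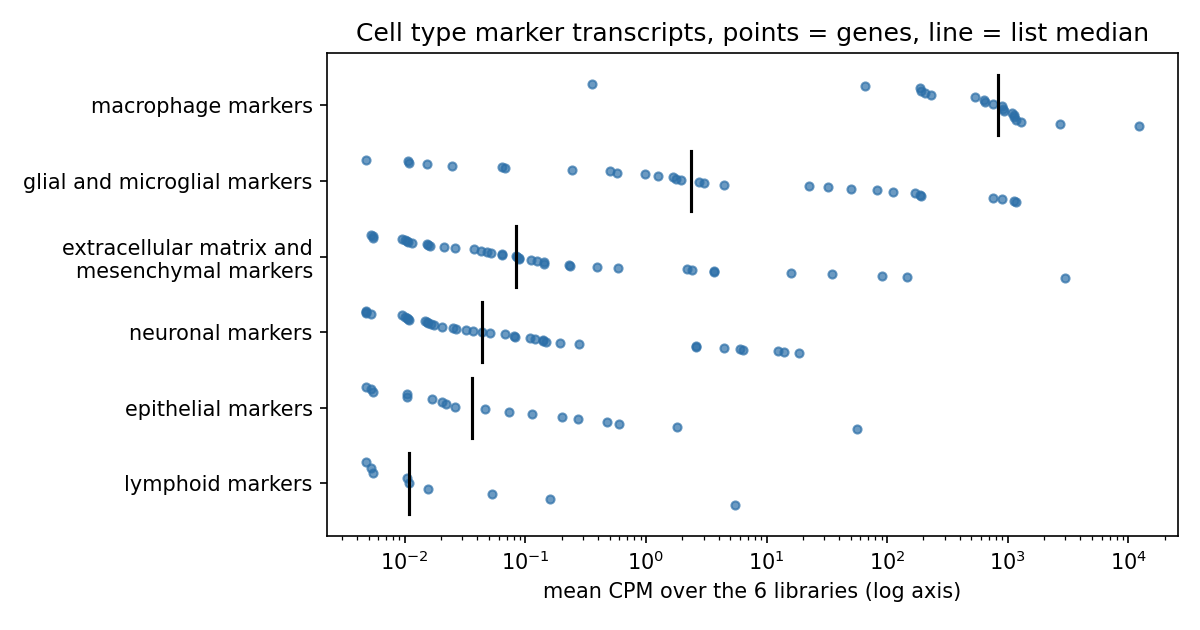
Mean CPM over the 6 libraries (horizontal log axis) of the marker genes of 6 cell type lists; each point is a gene and the black line is the list's median. The macrophage markers have a median of 823 CPM and the neuronal markers one of 0.0436 CPM.

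Of 12611 genes tested across the transcriptome with edgeR's quasi-likelihood test, 0 passed an adjusted p of 0.05, and the smallest adjusted p was 0.0949. At an unadjusted p under 0.05 there were 534 genes, 304 higher and 230 lower in the libraries labelled NR3C1, where chance alone would give 630.55. That count rested on the libraries used: it was 839, 947 and 671 without control replicates 1, 2 and 3 and 340, 461 and 328 without NR3C1 replicates 1, 2 and 3. In 10.3% of genes the CPM of the groups did not overlap, 659 higher and 644 lower, against the 10% that chance gives. limma-voom also called 0 genes, DESeq2 called 23, of which 22 were higher, and edgeR's exact test, added after the data were seen, called 29. With no filter on low counts the quasi-likelihood test called 65 genes, 59 higher and 6 lower. They included Yam1, named after its values were seen, whose counts were high in NR3C1 replicate 3 only. Its adjusted p was 1.52e-53 with no filter and 0.998 with the filter, so p-values with no filter need caution. Without control replicate 2 the quasi-likelihood test called 30 genes, without NR3C1 replicate 1 it called 3, and without NR3C1 replicate 3 it called 1. In simulated counts of this design, 12514 genes in 3 libraries against 3, the same test recovered 62% of genes changed 1.25-fold, 86% of those changed 1.5-fold and 100% of those changed 2-fold. The simulated changes were placed in genes with higher counts, many at once, and each gene varied independently. These shares need not hold for the real libraries, where Ifit3, at 1.31-fold, was not called by this test (adjusted p = 0.118). The count of 0 calls thus does not exclude changes of 1.25-fold to 1.5-fold. It does not exclude larger ones either, as the same test left Hist1h1a, at 2.28-fold, uncalled (adjusted p = 0.366). Gm26870, named after its values were seen, was also not called at 57.8-fold (adjusted p = 0.0949).

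Interferon-stimulated genes, the antiviral and immune-sensing genes that type I and type II interferons induce, rose as a group in the libraries labelled NR3C1. The list passed camera with an adjusted p of 1.06e-38 under a preset correlation of 0.01 between genes, but not with a correlation estimated from the 6 libraries (adjusted p = 0.231 with an estimated correlation). Under the preset correlation a grouping that mixes the labels also gave an unadjusted camera p of 1.96e-15, so the size of such p-values needs caution. Of 68 tested members 63 had a positive log2 fold change, with a median of 0.17, and the mean log2 CPM of the list was between 6.66 and 6.76 in the control libraries and between 6.84 and 6.94 in the others. Adjusted over the list alone, 33 members were higher and 1 lower by edgeR's quasi-likelihood test, and over all genes tested 0 were, where DESeq2 and edgeR's exact test each called 8 members. Ifit3, an antiviral effector, was at 210.0 ± 7.81 CPM in the control libraries and 275 ± 22.01 CPM in the libraries labelled NR3C1 (SD, n = 3 each), a log2 fold change of 0.39 ± 0.06 (SE). Its adjusted p from the quasi-likelihood test was 0.118 over all genes and 0.00238 over the list alone. Over all genes it was 4.00e-05 with DESeq2 and 0.00013 with edgeR's exact test, and Ifit3 was also called with no filter on low counts (4.85e-08) and without control replicate 2 (0.0107). All p-values with no filter need the caution given above for Yam1. Gbp4, an interferon-induced guanylate-binding protein, went from 10.0 ± 1.36 to 14.7 ± 0.457 CPM, a log2 fold change of 0.55 ± 0.10 (SE), with an adjusted p from the quasi-likelihood test of 0.191 over all genes and 0.00399 over the list alone. Over all genes it was 0.00821 with DESeq2, 0.000586 with edgeR's exact test, 4.67e-05 with no filter on low counts and 0.0263 without control replicate 2. Members of such families share similar sequence, so reads could be split between copies in ways the counting tool, which is not given in the sources used here, decides. The 1 lower member was Ifi27, named after its values were seen, at 34.8 ± 3.37 and 28.8 ± 0.721 CPM.

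In limma's rotation test fry, which asks whether a list's genes move on balance one way and does not compare them with other genes, the interferon-stimulated genes had an adjusted p of 0.0813. The count adjusted over the list alone rested on the libraries used: without NR3C1 replicate 1 it was 6 higher and 0 lower, without NR3C1 replicate 3 it was 15 higher and 0 lower, and without control replicate 2 it was 47 higher and 2 lower.

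Inflammatory transcription factors, the group the series names, were divided between both directions. Of 68 tested members 32 were positive and 36 negative, the median log2 fold change was -0.01, and camera gave an adjusted p of 0.856. Adjusted over the list alone 0 members passed edgeR's quasi-likelihood test, 3 were at an unadjusted p under 0.05, all higher, and over all genes the count was 0. Stat2, which carries the interferon signal to the nucleus, was at 116 ± 2.21 CPM in the control libraries and 131 ± 5.04 CPM in the libraries labelled NR3C1, a log2 fold change of 0.17 ± 0.05 (SE). Its adjusted p from that test over all genes was 0.735. The list shares 4 of its tested members with the interferon-stimulated genes. Its test pointed up, without passing, when control replicate 1, control replicate 2 or NR3C1 replicate 3 was left out (adjusted p = 0.717, 0.882 and 0.852).

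Inflammatory cytokines and NF-kB target genes rose as a group by a smaller amount. Of 57 tested members 40 were positive, the median log2 fold change was 0.05, and camera gave an adjusted p of 1.92e-05. The call was lost with an estimated correlation (adjusted p = 0.330) and in fry (adjusted p = 0.314). The mean log2 CPM of the list was 5.53, 5.38 and 5.51 in control replicates 1, 2 and 3 and 5.59, 5.53 and 5.56 in NR3C1 replicates 1, 2 and 3, and without control replicate 2, the lowest, the median was 0.04 and the adjusted p 0.0387. The list shares 0 tested members with the interferon-stimulated genes. Adjusted over the list alone 0 members passed edgeR's quasi-likelihood test, and at an unadjusted p under 0.05 there were 10 higher and 2 lower. Saa3, an acute-phase serum amyloid, was at 6.59 ± 0.361 CPM in the control libraries and 8.61 ± 0.166 CPM in the libraries labelled NR3C1, a log2 fold change of 0.38. Il15, a cytokine that sustains natural killer and memory T cells, was at 14.0 ± 1.46 and 17.8 ± 1.66 CPM, a log2 fold change of 0.34.

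Glucocorticoid receptor induced genes did not pass the list test. Of 37 tested members 17 were positive and 20 negative, with a median log2 fold change of -0.01 and a mean of 0.04, and camera, which pointed up, gave an adjusted p of 0.296. The sign of that median was not stable, as it was 0.0075 without control replicate 1, 0.0057 without control replicate 2 and 0.03 without NR3C1 replicate 1, while the list did not pass in any of these (adjusted p = 0.260, 0.343 and 0.338). The mean log2 CPM of the list was between 4.23 and 4.27 in the control libraries and between 4.27 and 4.29 in the others, with all 3 libraries labelled NR3C1 above all 3 controls, an order that chance gives in 10% of cases counting both directions. Adjusted over the list alone 0 members passed edgeR's quasi-likelihood test, with 6 at an unadjusted p under 0.05, all higher. Lcn2, an iron-sequestering lipocalin, was at 79.5 ± 8.44 CPM in the control libraries and 92.9 ± 2.18 CPM in the libraries labelled NR3C1, and Tnfaip3, an inhibitor of NF-kB signalling, at 8.41 ± 0.813 and 10.4 ± 0.607 CPM. The log2 fold changes were 0.22 and 0.30, and the adjusted p from that test over all genes was 0.831 and 0.888.

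Splicing factors lay slightly lower against all other genes in camera with the preset correlation, but their level overlapped between the groups. The mean log2 CPM of the list was 6.57, 6.46 and 6.54 in control replicates 1, 2 and 3 and 6.48, 6.49 and 6.52 in NR3C1 replicates 1, 2 and 3. Of 96 tested members 58 were negative and 38 positive, the median log2 fold change was -0.01, and camera gave an adjusted p of 0.0261. The call ended with an estimated correlation (adjusted p = 0.404), in fry (adjusted p = 0.581) and with no filter on low counts (adjusted p = 0.0719). Adjusted over the list alone 0 members passed edgeR's quasi-likelihood test, with 3 at an unadjusted p under 0.05, all lower. Luc7l2, a factor of the U1 small nuclear ribonucleoprotein, was at 113 ± 8.05 CPM in the control libraries and 100.3 ± 4.50 CPM in the libraries labelled NR3C1, a log2 fold change of -0.17. The call also ended without control replicate 1, control replicate 3, NR3C1 replicate 1 or NR3C1 replicate 2, where the adjusted p was 0.662, 0.185, 0.125 and 0.102. The median log2 fold change was 0.0004 without control replicate 1, -0.0041 without control replicate 3 and -0.0046 without NR3C1 replicate 1. It was -0.04 without control replicate 2 (adjusted p = 1.01e-06) and -0.03 without NR3C1 replicate 3 (adjusted p = 0.00334).

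**Figure D3:**
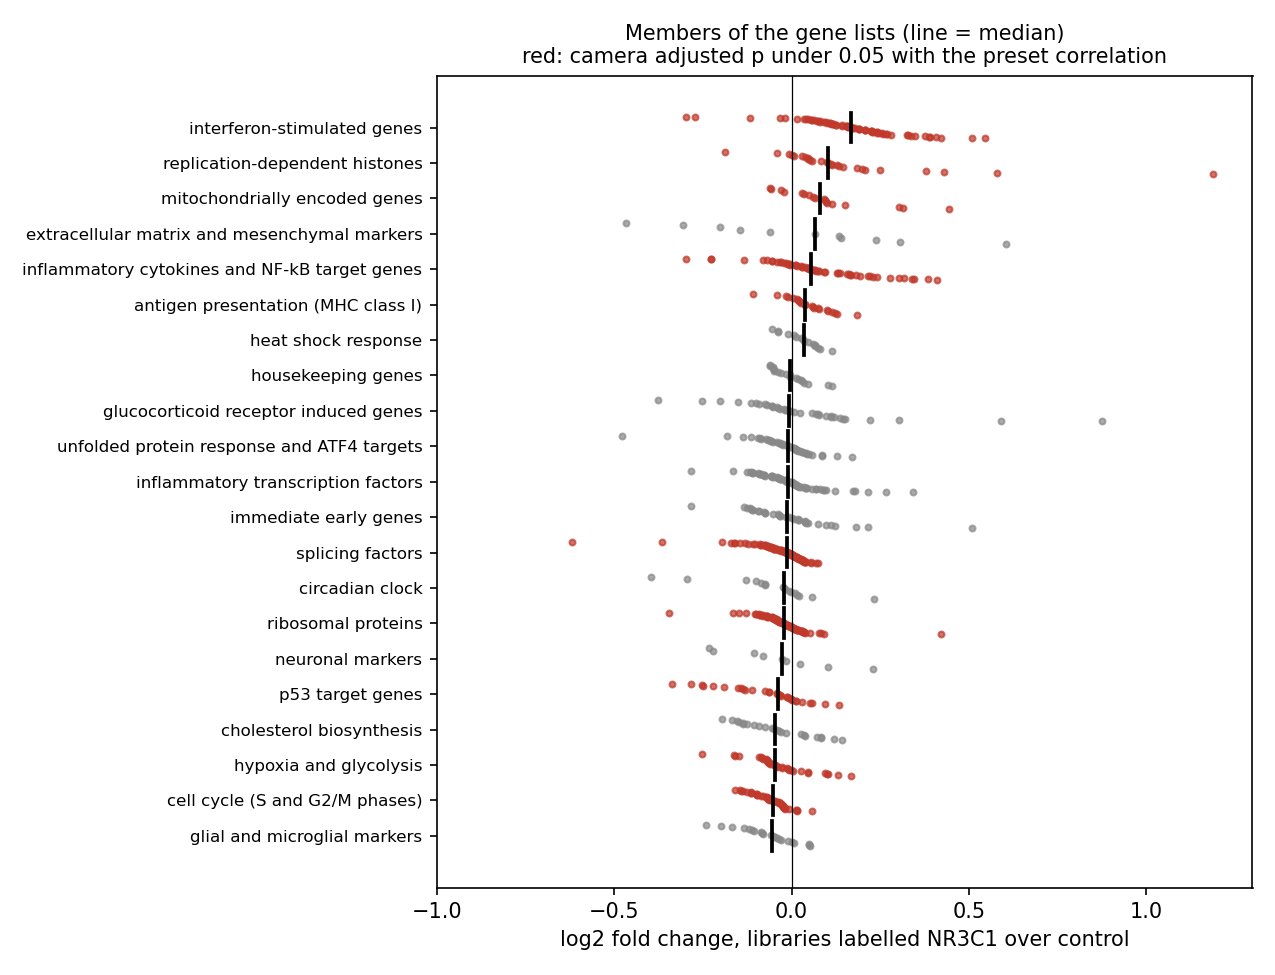
Log2 fold change between the libraries labelled NR3C1 and the control libraries (horizontal axis) for the tested members of the 21 gene lists with at least 5 tested members; each point is a gene, the black line is the list median, and red marks an adjusted camera p under 0.05 with the preset correlation. The interferon-stimulated genes have a median of 0.17, and 63 of their 68 members lie above 0.

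Of the 16 other lists tested, 3 rose and 4 fell by camera with the preset correlation, all by small amounts. Genes of antigen presentation by MHC class I rose (adjusted p = 0.00347, or 0.404 with an estimated correlation, 19 of 23 positive, median log2 fold change 0.04). Adjusted over the list alone 0 of its members passed edgeR's quasi-likelihood test, and 1 was at an unadjusted p under 0.05, H2-T22, at 176 ± 18.4 and 200.1 ± 19.0 CPM (adjusted p over all genes = 0.998). Replication-dependent histone genes rose (adjusted p = 0.00142, or 0.231 with an estimated correlation, 24 of 27 positive, median 0.10), with Hist1h1a at 0.446 ± 0.0898 and 1.01 ± 0.0236 CPM, a gene that edgeR's exact test called (adjusted p = 0.0148) and that passed the quasi-likelihood test over the list alone (adjusted p = 0.0151), but over all genes only with no filter on low counts (adjusted p = 0.0430). Cell cycle genes fell (adjusted p = 1.13e-05, or 0.404 with an estimated correlation, 40 of 44 negative, median -0.05). No cell cycle gene passed the quasi-likelihood test over the list alone, 3 were at an unadjusted p under 0.05, and the mitotic kinesin gene Kif20a was at 78.5 ± 3.08 and 70.3 ± 2.26 CPM (adjusted p over all genes = 0.901). p53 target genes fell (adjusted p = 0.0183, or 0.231 with an estimated correlation, 24 of 32 negative, median -0.04). Of the 2 members with the smallest p, Gtse1, a cell cycle regulator, was at 46.7 ± 6.01 and 39.9 ± 2.95 CPM, while Mdm2, the ubiquitin ligase that targets p53, was on the other side at 251 ± 9.11 and 276 ± 11.8 CPM, and neither passed alone (adjusted p over all genes = 0.998 for each). Genes of hypoxia and glycolysis fell (adjusted p = 0.0217, or 0.404 with an estimated correlation, 27 of 36 negative, median -0.05). The lactate exporter gene Slc16a3, at 144 ± 12.8 and 129 ± 2.29 CPM, did not pass alone (adjusted p over all genes = 0.998). Mitochondrially encoded genes rose (adjusted p = 0.0272, or 0.564 with an estimated correlation, 14 of 18 positive, median 0.08) and ribosomal protein genes fell (adjusted p = 0.0284, or 0.838 with an estimated correlation, 57 of 83 negative, median -0.02).

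With an estimated correlation 0 of these 7 calls held, and in fry the p53 list held (adjusted p = 0.0023) and the other 6 did not. Control replicate 2 stood apart on the first principal component, which held 32.6% of the variance, at 25.0 against at most -0.97 in the others, and had 1.62% mitochondrial counts against 2.08% to 2.35%. Without it the mitochondrial list pointed down (median -0.06, adjusted p = 0.0511), the ribosomal proteins rose (median 0.01, adjusted p = 0.00941), the hypoxia list lost its call (median -0.0051, adjusted p = 0.298) and the antigen presentation list had a median of 0.08 (adjusted p = 3.72e-10). The mean log2 CPM of the antigen presentation list was 7.86 in control replicate 2, above 2 of the 3 NR3C1 libraries (7.87, 7.82 and 7.84), and 7.74 and 7.77 in control replicates 1 and 3. The cell cycle list kept its call without each library in turn, with a median of -0.03 without control replicate 2 or NR3C1 replicate 1 (adjusted p = 0.00107 and 0.0148) and of -0.08 without control replicate 1 (adjusted p = 8.21e-07). The antigen presentation, p53 and histone lists lost theirs without control replicate 1 (adjusted p = 0.273, 0.0684 and 0.0901), where the antigen presentation median was 0.02, the mitochondrial median 0.18 (adjusted p = 6.62e-05) and the ribosomal median -0.07 (adjusted p = 2.93e-10). Leaving out control replicate 3 ended the call of the ribosomal proteins (adjusted p = 0.185) and gave the p53 list a median of -0.07 (adjusted p = 0.0425). Leaving out NR3C1 replicate 1 gave the mitochondrial list a median of 0.13 (adjusted p = 0.000402) and the ribosomal proteins one of -0.04 (adjusted p = 0.000154). Leaving out NR3C1 replicate 2 ended those of the hypoxia and mitochondrial lists (adjusted p = 0.0511 for each) and turned the ribosomal list upward in the test (median -0.004, adjusted p = 0.954), and leaving out NR3C1 replicate 3 ended those of the hypoxia and mitochondrial lists (adjusted p = 0.0715 and 0.713, with a mitochondrial median of 0.02). With no filter on low counts the p53 and mitochondrial lists did not pass (adjusted p = 0.0719 and 0.264), nor did the mitochondrial list with a minimum of 1 CPM in 3 libraries (adjusted p = 0.0534) or with unfiltered FPKM (adjusted p = 0.446).

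The other 9 lists did not pass camera. The adjusted p was 0.0696 for glial and microglial markers, whose Csf1r was at 1187 ± 80.2 CPM in the control libraries and 1081 ± 25.9 CPM in the libraries labelled NR3C1. It was 0.125 for cholesterol biosynthesis, 0.149 for the heat shock response and 0.174 for extracellular matrix and mesenchymal markers, of which Dcn, the proteoglycan decorin, was at 1.74 ± 0.129 and 2.65 ± 0.06 CPM. Adjusted over that list alone, 2 matrix members were higher by edgeR's quasi-likelihood test, Dcn and Thbs1, the latter at 31.4 ± 4.96 and 38.9 ± 2.28 CPM. For the circadian clock the adjusted p was 0.227, for the unfolded protein response and ATF4 targets 0.600, for immediate early genes 0.712, for housekeeping genes 0.831 and for neuronal markers 0.856. Of the epithelial markers 4 were tested, too few for the list test. Some of these lists passed under other settings: the matrix markers rose with no filter on low counts (adjusted p = 0.0258) and with each form of the FPKM values (adjusted p from 0.0318 to 0.0450), the clock genes fell with unfiltered FPKM (adjusted p = 0.0450), and the heat shock genes rose without control replicate 3 (adjusted p = 0.0218).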

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

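The exact test of edgeR was added after the data were seen. The log2 fold change of Nr3c1 stayed positive and not called under all 17 alternatives, between 0.01 without control replicate 2 and 0.16 without control replicate 1. The count of called genes, 0 with the quasi-likelihood test of edgeR, moved to 23 with DESeq2 (22 higher, 1 lower), 65 with no filter on low counts (59 and 6), 29 with edgeR's exact test (24 and 5) and 4 with log2(FPKM + 1) and no filter (1 higher, Gm23751, and 3 lower, Mir23b, Snord37 and mt-Ta). It remained 0 with RLE or upper-quartile scaling, limma-voom, a 1 CPM minimum, FPKM with a minimum and the stricter thresholds. Of the calls, 8 with DESeq2, 18 with no filter and 8 with the exact test were in the interferon list. The calls with no filter also included Yam1, whose counts were high in NR3C1 replicate 3 only. Leaving out each library gave 0 to 30 called genes, 0 to 27 higher and 0 to 3 lower, with the most without control replicate 2. The 3 genes called without NR3C1 replicate 1 were Gm26870, Gm10800 and Gm10719, and the 1 called without NR3C1 replicate 3 was Gm26870, all named after their values were seen. The cause of these differences was not tested.

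With the replicate number as a block, 7 genes were called, 7 higher and 0 lower, 3 of them in the interferon list, and Nr3c1 had a log2 fold change of 0.10. Those 3 were Ifit2, Ifit3 and Gbp2 (quasi-likelihood adjusted p = 0.0286, 0.0364 and 0.0415). The others were Slfn1 (0.0286), Gm26870 (1.61e-08), Gm10800 and Gm10719 (0.000133 for each). Apart from Ifit3, all were named after their values were seen. The libraries share only a number: the same-number correlations of deviations from the group means were 0.011, 0.052 and 0.081, and 2 of 3 libraries in each group correlated best with their own number. The block ended the call of the ribosomal proteins (adjusted p = 0.0546) and no other list call.

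The interferon-stimulated genes kept their direction and call under every scaling, filter, unit, block and left-out library run, but not with an estimated correlation (adjusted p = 0.231) or fry (0.0813). The cytokine list likewise lost its call with these settings only (0.330 and 0.314). The splicing factors lost theirs with both (0.404 and 0.581) and with no filter (0.0719), and over the left-out libraries their adjusted p ran from 1.01e-06 to 0.662. The inflammatory transcription factors, at 0.542 to 0.979 over the left-out libraries, changed direction in 3 of them. The glucocorticoid receptor induced genes kept their side of the threshold throughout. The count of 7 other lists ran from 4 to 7 over the left-out libraries, was 0 with an estimated correlation and was 1 with fry.

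Directions reversed as follows, as adjusted p over the left-out libraries: unfolded protein response 0.311 to 0.898, immediate early genes 0.227 to 0.998, neuronal markers 0.672 to 0.941, mitochondrial genes 6.62e-05 to 0.713, ribosomal proteins 2.93e-10 to 0.954 and housekeeping genes 0.672 to 0.954. The neuronal list also reversed with no filter on low counts (0.991) and with log2(FPKM + 1) and no filter (0.729). The log2 fold change of Sfn, at under 1 CPM, ran from -0.30 to 0.0226. The cause was not tested. Of 738 other values of the 44 further named genes, 721 kept direction and side of the threshold, 14 passed it and 3 reversed, and of 256 values of the other lists 214 kept both, 6 passed, 27 fell short and 9 reversed. Depth limits the lowest genes: 12611 of 22493 genes had enough counts to test.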

Other observations

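The genes and families in the next 2 paragraphs were chosen after the results were seen, as were the tests of the macrophage explanations, of gene length and expression level and of the splits, and the readings of all values as tests of an explanation. The other values used below, from left-out libraries and other settings, the list tests and the Nr3c1 fold change, had been planned, apart from edgeR's exact test, which was added after the data were seen. Among genes outside the interferon list, 2 related families lay mostly on the positive side in the libraries labelled NR3C1. Of 11 tested guanylate-binding (Gbp) genes 5 are in the list, and the other 6 were all positive, with a median log2 fold change of 0.37. Of 7 tested Schlafen (Slfn) genes, none of them in the list, 6 were positive, with a median of 0.27. These counts were equal under TMM, RLE and upper-quartile scaling, but scaling shifts all genes by nearly the same amount, so this adds no support. Slfn1, a growth-regulatory Schlafen gene, was at 144 ± 12.1 CPM in the control libraries and 192 ± 16.8 CPM in the others (SD, n = 3 each), and the complement gene Cfb at 38.0 ± 1.56 and 47.3 ± 1.54 CPM. Ccl22, a chemokine that attracts T cells, was at 8.78 ± 1.61 and 13.7 ± 2.54 CPM. Over all genes the adjusted p of Slfn1, Cfb and Ccl22 was 0.191, 0.191 and 0.407 in edgeR's quasi-likelihood test with all libraries and the filter. It was 0.000272, 0.0142 and 0.0201 with DESeq2, and 0.000586, 0.00214 and 0.0153 in edgeR's exact test. The quasi-likelihood test called all 3, in that order, with no filter on low counts (4.53e-09, 0.00371 and 6.63e-07) and without control replicate 2 (0.0126, 0.0208 and 0.0139).

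The largest differences were in 3 predicted genes with few reads in the control libraries. Gm26870 had counts of 4, 13 and 24 in the control libraries and 171, 673 and 1505 in the libraries labelled NR3C1 (edgeR quasi-likelihood adjusted p = 0.0949). Gm10800 had 0, 2 and 1 against 20, 76 and 143, and Gm10719 had 0, 3 and 1 against 22, 91 and 198 (edgeR quasi-likelihood adjusted p = 0.118 for each). All 3 genes had their lowest NR3C1 count in replicate 1 and their highest in replicate 3, far apart within that group. They moved in parallel, so they do not stand for 3 independent differences. DESeq2 called all 3, Gm26870, Gm10800 and Gm10719 (adjusted p = 5.10e-05, 0.00224 and 0.00479), as did edgeR's exact test (adjusted p = 2.03e-12, 2.40e-11 and 1.30e-10). The quasi-likelihood test called them, in that order, with no filter on low counts (2.42e-300, 4.47e-48 and 5.46e-61) and without control replicate 2 (0.0107, 0.0107 and 0.0114). Yam1 was at 246983 counts in NR3C1 replicate 3 and between 37823 and 68800 in the other 5 libraries.

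All 6 libraries, labelled as a hippocampal neuronal line, held abundant macrophage transcripts, led by Lyz2 at 12231 CPM, Cd14 at 2717 and Msr1 at 1289. RNA of other cells in some libraries only is argued against by the median of the macrophage markers, which was 1.05 times as high in the highest as in the lowest library. A minority of macrophages among the labelled cells is argued against, as far as those cells express the listed markers, since at most 12.5% of the neuronal or of the matrix and mesenchymal markers reached 10 CPM. Whether all 6 libraries came from macrophage-like cells, microglia included, stays open as a candidate explanation: the median macrophage marker lay at the 99.3 percentile of listed genes, but that list was written after such transcripts had been seen, so this restates the pattern and tests nothing. Of the lists fixed in advance, the neuronal markers had a median of 0.0436 CPM, with 8 of 39 at 1 CPM or more and 0 at 100 CPM. Of the 30 glial and microglial markers, also fixed in advance, 19 averaged 1 CPM or more and 8 averaged 100 CPM or more. Its highest members, named after their values were seen, were Cd68 at 1177 CPM, Csf1r at 1134 and Itgam at 889. All 3 are also macrophage markers, while the microglial genes Tmem119 and P2ry12 averaged 0.984 and 2.77 CPM. The neuronal values argue against RNA mostly from cells that express the listed neuronal markers, whatever the label. Whether the labelled line itself lacks those markers and carries the macrophage transcripts is not answered by these tables.

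The rise of the interferon-stimulated genes does not rest on control replicate 2 alone, since without it the median log2 fold change was 0.14, against 0.17 with all libraries. A trend with gene length or expression level would move other genes of like length and level as well, and is argued against as the whole cause: in 1000 draws of genes outside the list matched on both, the highest median log2 fold change was 0.0335. Activity of the transfected receptor, the biological explanation the design names, cannot be told apart from a response of the cells that differs between plasmid preparations, as each group received its own plasmid, and the glucocorticoid receptor induced genes did not decide it (camera adjusted p = 0.296). Over its alternatives the adjusted p of the interferon list ran from 1.61e-42 to 0.231.

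The counted Nr3c1 was not detectably higher in the libraries labelled NR3C1. Too few reads to see a rise is argued against, since the upper bound of the 95% interval was 1.23-fold. A plasmid transcript that is not counted under mouse Nr3c1, for example one whose sequence aligns poorly to the mouse gene, could leave the counted log2 fold change at 0.10 and stays open, since the tables hold no reads outside the gene models.

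With 3 libraries against 3 there are 10 splits, so a share under 0.05 cannot be reached and the splits cannot exclude chance. The real split called 0 genes, higher 0 and lower 0, and so did the other splits at most, so 10 of 10 splits gave as many in each case. For the interferon list 1 of 10 splits, the real one, had a camera p as small, 5.05e-40 against 1.96e-15 for the smallest of the others. For the cytokine list it was 1 of 10 (2.74e-06 against 1.17e-05), for the splicing factors 4 of 10 (0.00995 against 3.03e-06), for the glucocorticoid receptor induced genes 3 of 10 (0.226 against 0.217) and for the inflammatory transcription factors 9 of 10 (0.856 against 0.118). The real split passed 7 of the other lists and the highest of the other splits 4, so 1 of 10 splits gave as many. For the interferon list, splits that mix the labels also gave small camera p-values, such as 1.32e-11 and 4.95e-08, while the largest was 0.836. The median log2 fold change was 0.11 and -0.07 in the former, against 0.17 in the real split. A small camera p with the preset correlation thus did not need the real grouping.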
